A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

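RNA of BY4741 yeast cultures was measured on 12 Affymetrix GeneChip Yeast Genome 2.0 arrays, 3 in each of 4 groups: untreated controls and cultures with 110 mg/L alachlor from the LOEC experiment, and untreated controls and cultures with 200 mg/L alachlor from the IC20 experiment, all after 2 h. The deposited values are intensities on a linear scale, made by the authors from 1-colour biotin-labelled arrays. Affymetrix Expression Console is named in the submitters' processing notes with no version or role. How probes were summarized and arrays normalized is not given in the sources used here. The array medians lie within 1561.3 to 1613, values run from 0.79 to 38940.6, and 27 of 68592 values sit at exactly 1. Log2 of the values was taken with no pseudocount.

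The table held 5716 probe sets. A probe set table for the array tied 5498 of them to 1 S. cerevisiae gene, 0 to several genes, and left 218 unnamed. Names were matched to the RefSeq gene table (assembly R64, used for names and coding lengths only), which updated 12 symbols and matched all 5449 genes. For 47 genes with several probe sets the one with the highest mean over the 12 arrays was used, so that 49 probe sets were left out. The probe sets of 2 of these genes at 110 mg/L and of 5 at 200 mg/L differed in whether they passed, and 0 passed in opposite directions. Probe sets marked by the manufacturer as shared between similar sequences stand for 100 genes, and those marked as cross-hybridizing for 17. The unnamed probe sets were left out of the tests of genes and are described separately. No positions on the genome are given, since the build behind the array is not given in the sources used here.

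Each gene was fitted in limma 3.58.1 (R 4.3.3) with 4 group means, and the moderated test of eBayes was applied to 4 contrasts: 110 mg/L minus LOEC controls, 200 mg/L minus IC20 controls, the difference of these responses, and IC20 controls minus LOEC controls. All 12 arrays share the estimate of the spread, with 8 residual degrees of freedom and 2.73 prior ones. P values were adjusted by the Benjamini-Hochberg method over the 5449 genes, two-sided, and a gene passed at adjusted p under 0.05. On 3 arrays against 3 an exact permutation test cannot give p below 0.1, so none is reported for single genes. In 39 gene lists, written from general knowledge of yeast, the members past the test were counted over all genes and adjusted over the list alone, and each list was tested with camera in limma at a preset correlation of 0.01 between genes, adjusted over the lists within a contrast, and again with the correlation estimated for each list. Lists held at least 4 measured genes. After the data were seen, changes of named genes over a group with an array below 228.8, the highest reading of LEU2, URA3 and MET17, were bounded by the brighter mean over the higher of 228.8 and the dimmer mean, with no fold where both means lay below.

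Groups, contrasts, thresholds, gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except the alternatives named as chosen after seeing the data. The rule named, at each dose, the 10 largest rises and 10 largest falls past the test with all 3 treated arrays on the same side of all 3 controls. In each list up to 4 members with the largest changes past the test at either dose. The 5 largest differences between doses in each direction. And, as values, the members of the lists of mating type and of loci deleted in the strain. It gave 161 genes. Other genes are said to be named after their values were seen.

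The procedure was tested on simulated data with changes of known size put into a part of the genes. A log2 change of 0.5 was recovered in 89.6% of genes at 110 mg/L, 91% at 200 mg/L and 77.6% for the difference. A change of 1 was recovered in 97%, 100% and 97.8%. There were 9, 9 and 15 false calls, and 0 calls in the contrast of controls, where none had been put in. The simulated noise was independent between genes and arrays, with the same spread for a gene in all groups and no difference between the experiments. The real arrays had unequal spreads, trends with coding length and deviations shared between arrays. These rates thus check the procedure and do not give the error rate in these data. The alternatives were quantile normalization, median centring, leaving out the 20% dimmest probe sets, all probe sets of the table, an intensity trend with robust moderation, only the 6 arrays of an experiment, array weights, the replicate number as a block, adjusted p under 0.01, a change of at least 2-fold, log2 of the value plus 16, and leaving out each array in turn. Chosen after seeing the data were the removal of each array's trend with coding length (lowess), and leaving out IC20 control array 2 and 200 mg/L array 1 together.

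Other splits of the arrays were fitted in the same way: all 10 splits of 6 arrays for each dose and for the controls, and for the difference 100 of 200 regroupings, drawn with seed 1, in which the experiment labels were exchanged among the control arrays and among the treated arrays. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.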

Results

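The data are 12 Affymetrix Yeast Genome 2.0 arrays of Saccharomyces cerevisiae BY4741, a haploid laboratory strain of mating type a, grown in minimal medium. Cultures were exposed for 2 h to alachlor, a chloroacetanilide herbicide, at 110 mg/L, which the submitters call the LOEC, or at 200 mg/L, which they call the IC20. Each dose was a separate experiment with its own untreated controls, so the arrays fall into 4 groups of 3 biological replicates: LOEC controls, 110 mg/L, IC20 controls and 200 mg/L. The array medians lay between 1561.3 and 1613 intensity units. Replicates correlated across probe sets at r = 0.993 to 0.9983, and the median SD of a gene within a group, on the log2 scale, was 0.0559 in the LOEC controls, 0.0566 at 110 mg/L, 0.0823 in the IC20 controls and 0.0947 at 200 mg/L. In the IC20 experiment the deviations of the arrays from their group means followed the coding length of the genes, with Spearman's rho across genes from -0.488 to 0.57, against -0.078 to 0.152 in the LOEC experiment. Probe sets of LEU2, URA3 and MET17, deleted in the strain, read up to 228.8, and a change over a group that reads at that level is given as a lower bound, the brighter mean over 228.8 or over the dimmer mean if that is higher. The number of arrays limits the precision: values of 3 arrays against 3 are given with the limma test, which shares its estimate of the spread over all 12 arrays. A group of genes is said to shift when camera, a limma test of a gene list against all other genes, passed after adjustment over the 39 lists. In splits that mix treated and control arrays, up to 11 lists also passed at 110 mg/L and up to 17 at 200 mg/L. With an estimated correlation 4 lists passed at 110 mg/L, 1 at 200 mg/L and 1 for the difference. A shift at the preset correlation alone is thus weak evidence.

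The comparison at 110 mg/L asks which transcripts respond to the lower dose. Targets of the pleiotropic drug resistance factors, among them RSB1, GRE2, ICT1 and YOR1, and some genes of iron uptake, phosphate supply and sulfur metabolism rose, while the wall genes CWP1 and WSC4, the aldehyde dehydrogenases ALD4 and ALD6 and the glucose transporter HXT7 fell. RSB1 (YOR049C), a membrane protein that exports sphingoid long-chain bases, rose at least 9.07-fold, from an intensity of 224 ± 2.68 to 2076 ± 67.5 (SD, n = 3; log2 change 3.21, SE 0.061, adjusted p = 1.57e-10). Its controls read at the level of the deleted loci, so the fitted log2 change is not exact. GRE2 (YOL151W), a methylglyoxal reductase, rose 3.60-fold, from an intensity of 2767 ± 84.9 to 9951 ± 275 (SD, n = 3; log2 change 1.85, SE 0.043, adjusted p = 6.27e-10). YGP1, a secreted glycoprotein made when nutrients run low, rose 3.52-fold, and the RNA-binding protein gene TIS11, which lowers iron-using transcripts in iron shortage, rose 2.96-fold (log2 changes 1.81 and 1.57, SE 0.084 and 0.078). EEB1 (YPL095C), an acyltransferase of ethyl ester synthesis, fell to 0.374 of its control level, from an intensity of 4403 ± 160 to 1647 ± 88.9 (SD, n = 3; log2 change -1.42, SE 0.050, adjusted p = 2.81e-08).

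The other largest rises at 110 mg/L were those of the acyltransferase gene ICT1 (log2 change 1.58), the ABC exporter YOR1 (1.36), the uncharacterized YGR035C (1.30), CIS1 (1.25), the mitochondrial pyruvate carrier subunit MPC3 (1.17) and the putative alcohol dehydrogenase BDH2 (1.14). The other largest falls were those of the uncharacterized YBL029W (-1.21), the cell wall mannoprotein CWP1 (-1.18), the cell wall sensor-like gene WSC4 (-1.13), PDR12, an ABC exporter of weak organic acids (-1.11), and HXT7, a high-affinity glucose transporter read by a probe set shared with near-identical sequences (-0.89). Smaller falls followed in ICS2 (-0.64), RPI1 (-0.61) and the aldehyde dehydrogenases ALD4 (-0.57) and ALD6 (-0.55). In each of these genes all 3 treated arrays lay on the same side of all 3 controls, as the rule that chose them required. Chance alone gives such a separation in 10% of genes, and as a condition of the choice it adds no support here.

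Drug resistance and iron uptake were the groups with the most members past the test at 110 mg/L. Of the 16 measured targets of Pdr1 and Pdr3, the transcription factors of pleiotropic drug resistance, 11 rose and 0 fell (13 and 1 adjusted over the list alone): median log2 change 0.78, adjusted p = 1.49e-22, and adjusted p = 0.00175 with an estimated correlation, which kept the call. The exporter gene PDR5 rose 1.96-fold. Its close relatives PDR10 and PDR15, and also PDR18, had log2 changes of -0.18, -0.24 and 0.015 that did not pass. PDR5, PDR15 and PDR18 are given here after their values were seen. The list of drug antiporters did not pass: of 18 genes, 3 rose and 1 fell (4 and 1 adjusted over the list alone), with a median log2 change of 0.077 and adjusted p = 0.138. Of 27 measured genes of the iron regulon of Aft1 and Aft2, 12 rose and 0 fell (17 and 1 adjusted over the list alone): median log2 change 0.27, adjusted p = 2.57e-15, and adjusted p = 0.00697 with an estimated correlation, which kept the call. TIS11, the cell wall mannoprotein FIT2 (1.04), which retains siderophores, the heme oxygenase HMX1 (0.66) and the ferric reductase FRE4 (0.52) were among them, while the iron permease FTR1 had a log2 change of -0.21 (adjusted p = 0.0580).

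Other lists that shifted up at 110 mg/L had smaller median changes. Among 36 genes of sulfur amino acid metabolism, 7 rose and 0 fell (12 and 2 adjusted over the list alone): median log2 change 0.10, adjusted p = 0.00179, and adjusted p = 0.208 with an estimated correlation. The cystathionine beta-lyase STR3 rose by a log2 change of 1.04. The regulator MET28 and the homoserine acetyltransferase MET2 rose at least 1.80-fold and 1.17-fold over controls at the level of the deleted loci. For zinc and phosphate starvation, 4 rose and 1 fell (11 and 1 adjusted over the list alone) of 21 genes: median log2 change 0.15, adjusted p = 0.000133, and adjusted p = 0.123 with an estimated correlation. The secreted acid phosphatases PHO5 (1.05) and PHO11 (0.87, on a probe set shared with similar sequences) and the phosphate transporter PHO89 (0.99) rose. In vitamin B1 and B6 metabolism, 4 rose and 1 fell (5 and 1 adjusted over the list alone) of 17 genes: median log2 change 0.094, adjusted p = 0.0158, and adjusted p = 0.0979 with an estimated correlation. SNO1, of vitamin B6 synthesis, rose (0.39) and PHO3, an acid phosphatase of thiamine supply, fell (-0.52). Of 20 glycolysis genes, 3 rose and 0 fell (3 and 0 adjusted over the list alone): median log2 change 0.057, adjusted p = 0.000564, and adjusted p = 0.192 with an estimated correlation. All 31 measured genes of the G1 and S phases of the cell cycle had positive changes but 0 rose and 0 fell (0 and 0 adjusted over the list alone), with 15 under an unadjusted p of 0.05 in limma. The list shifted up: median log2 change 0.13, adjusted p = 8.13e-07, and adjusted p = 0.0326 with an estimated correlation, which kept the call. In the later phases, G2, M and M/G1, 3 rose and 0 fell (5 and 0 adjusted over the list alone) of 32 genes: median log2 change 0.074, adjusted p = 0.00118, and adjusted p = 0.323 with an estimated correlation. DSE4, a glucanase of daughter cell separation, rose (0.38).

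Shifts up of 3 further lists at 110 mg/L were lost when some single array was left out, in fits that also have fewer arrays. Of 5 measured aryl-alcohol dehydrogenases, 0 rose and 0 fell (2 and 0 adjusted over the list alone), with 2 under an unadjusted p of 0.05 in limma: median log2 change 0.17, adjusted p = 0.0437, and adjusted p = 0.480 with an estimated correlation. Its call was lost without LOEC control array 1 (adjusted p = 0.118), 110 mg/L array 1 (adjusted p = 0.0963) and 110 mg/L array 3 (adjusted p = 0.0695), and with quantile normalization (adjusted p = 0.0586) or the length trend removed (chosen after seeing the data, adjusted p = 0.0654). Of 46 amino acid biosynthesis genes under Gcn4, 1 rose and 0 fell (7 and 0 adjusted over the list alone): median log2 change 0.038, adjusted p = 0.0143, and adjusted p = 0.551 with an estimated correlation. The call was lost without LOEC control array 1 (adjusted p = 0.0934) and 110 mg/L array 1 (adjusted p = 0.0963), and with median centring (adjusted p = 0.0657). Of 38 genes of cell wall integrity, 5 rose and 1 fell (9 and 2 adjusted over the list alone): median log2 change 0.049, adjusted p = 0.0378, and adjusted p = 0.265 with an estimated correlation. Without LOEC control array 3 (adjusted p = 0.0837), 110 mg/L array 2 (adjusted p = 0.0544) and 110 mg/L array 3 (adjusted p = 0.0523) this call was lost, as it was with median centring (adjusted p = 0.0527) and with the length trend removed (adjusted p = 0.0617). CWP1 is the member that fell.

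The 5 lists that shifted down at 110 mg/L were those of the proteasome, heat shock and chaperones, ribosome biogenesis, peroxisome and beta-oxidation, and phospholipid synthesis. Of 35 proteasome genes, 0 rose and 1 fell (0 and 0 adjusted over the list alone): median log2 change -0.073, adjusted p = 8.13e-07, and adjusted p = 0.0259 with an estimated correlation, which kept the call. Of 31 heat shock and chaperone genes, 1 rose and 3 fell (2 and 7 adjusted over the list alone): median log2 change -0.10, adjusted p = 0.000165, and adjusted p = 0.0852 with an estimated correlation. In ribosome biogenesis, 0 rose and 0 fell (0 and 0 adjusted over the list alone) of 77 genes, with 7 under an unadjusted p of 0.05 in limma: median log2 change -0.065, adjusted p = 2.59e-06, and adjusted p = 0.480 with an estimated correlation. Peroxisome and beta-oxidation genes numbered 19, of which 1 rose and 2 fell (2 and 8 adjusted over the list alone): median log2 change -0.14, adjusted p = 0.00224, and adjusted p = 0.0703 with an estimated correlation. The enoyl-CoA isomerase ECI1 fell (-0.46). In phospholipid synthesis under Ino2 and Ino4, 0 rose and 2 fell (0 and 2 adjusted over the list alone) of 22 genes: median log2 change -0.055, adjusted p = 0.00395, and adjusted p = 0.0852 with an estimated correlation.

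In all, 232 of 5449 genes passed at 110 mg/L by limma with Benjamini-Hochberg adjusted p under 0.05: 166 rose (71.6%) and 66 fell, 14 and 5 of them by at least 2-fold. The split was 149 higher and 94 lower (61.3% higher) after quantile normalization and 126 and 94 (57.3%) after median centring. With array weights, whose estimation stopped before convergence, 2132 genes passed, 1281 higher and 851 lower. The count was 133 without LOEC control array 1, 113 without LOEC control array 2, and 117, 154 and 135 without 110 mg/L arrays 1, 2 and 3.

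At 200 mg/L the question is which transcripts respond to the higher dose. The same drug resistance genes stood at the top, with larger changes, and INO1 and some glutathione transferases, aryl-alcohol dehydrogenases and nitrogen supply genes rose as well. RSB1 rose at least 17.5-fold, from an intensity of 232 ± 14.4 to 4065 ± 304 (SD, n = 3; log2 change 4.13, SE 0.061, adjusted p = 9.87e-12), where 1 of its 3 controls read below 228.8 and the others just above. GRE2 rose 6.60-fold, from an intensity of 2626 ± 100 to 17330 ± 302 (SD, n = 3; log2 change 2.72, SE 0.043, adjusted p = 9.87e-12). INO1 (YJL153C), which makes inositol phosphate, the first step of inositol synthesis, rose 4.21-fold, from an intensity of 463 ± 61.9 to 1943 ± 156 (SD, n = 3; log2 change 2.07, SE 0.090, adjusted p = 5.70e-08). The iron permease gene FTR1 (YER145C) fell to 0.502 of its control level, from an intensity of 6264 ± 262 to 3146 ± 234 (SD, n = 3; log2 change -0.99, SE 0.055, adjusted p = 3.75e-07).

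Other large rises at 200 mg/L were those of CIS1 (log2 change 2.48), RTA1, a membrane protein of the family of RSB1 (at least 2.65-fold over controls below 228.8), YGP1 (2.26), ICT1 (2.23), YOR1 (2.08), MPC3 (2.07) and BDH2 (2.06). The largest falls were those of YBL029W (at least 2.54-fold, to a level below 228.8), WSC4 (at least 3.53-fold, with 1 treated array below it), EEB1 (-1.80), CWP1 (-1.53), RPI1 (-1.27), PHO3 (-1.18), HXT7 (-1.16), FTR1, the biotin synthesis gene BIO4 (-0.96) and PDR12 (-0.95). All 3 treated arrays lay on the same side of all 3 controls in each of them, as the rule that chose them required.

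Among the 16 Pdr1 and Pdr3 targets at 200 mg/L, 15 rose and 0 fell (15 and 0 adjusted over the list alone): median log2 change 1.14, adjusted p = 1.64e-24, and adjusted p = 0.00129 with an estimated correlation, which kept the call. PDR5 rose 2.16-fold and PDR10 2.24-fold, and PDR18 alone did not pass (log2 change 0.007). Of 18 drug antiporters, 7 rose and 2 fell (9 and 2 adjusted over the list alone): median log2 change 0.11, adjusted p = 0.00997, and adjusted p = 0.448 with an estimated correlation. The polyamine exporters TPO4 (0.90) and TPO1 (0.63), QDR3 (0.56) and FLR1 (0.54) rose. Of 27 iron regulon genes, 12 rose and 2 fell (14 and 4 adjusted over the list alone): median log2 change 0.18, adjusted p = 0.00101, and adjusted p = 0.234 with an estimated correlation. FIT2 (1.24), TIS11 (1.24) and HMX1 (1.18) rose as FTR1 fell. FET3, the oxidase that works with the permease, had a log2 change of -0.20 that did not pass and is named here after its value was seen.

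**Figure D1:**
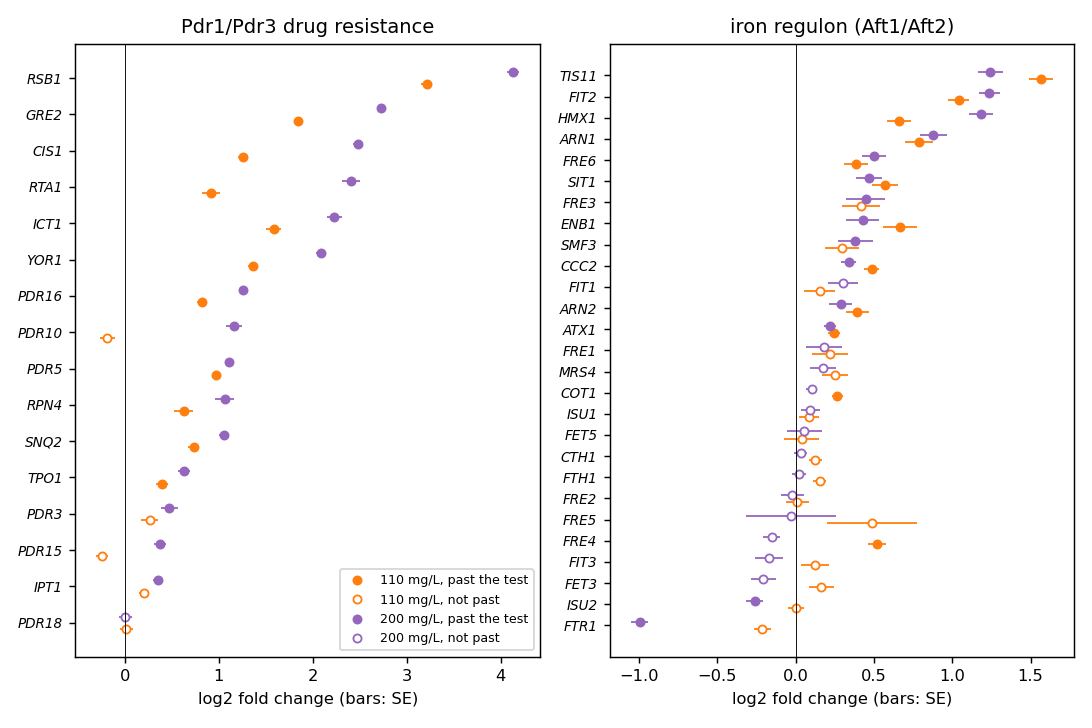
Log2 fold change of each measured gene of the Pdr1 and Pdr3 list (left) and of the iron regulon (right) at 110 mg/L (orange) and 200 mg/L (purple), each against the controls of its own experiment. Bars are the SE of the limma fit, and filled points passed at adjusted p under 0.05. RSB1 changed the most, by at least 9.07-fold and 17.5-fold, and FTR1 fell at 200 mg/L by 0.99.

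Lists of genes that handle reactive compounds shifted up at 200 mg/L at the preset correlation. Of 24 genes of glutathione synthesis, transfer and conjugate transport, 7 rose and 1 fell (9 and 1 adjusted over the list alone): median log2 change 0.073, adjusted p = 0.00812, and adjusted p = 0.133 with an estimated correlation. The glutathione transferases ECM4 (0.90) and GTT2 (0.67) rose. Of 25 oxidative stress genes under Yap1, 11 rose and 2 fell (12 and 2 adjusted over the list alone): median log2 change 0.086, adjusted p = 0.00331, and adjusted p = 0.234 with an estimated correlation. PRX1, a mitochondrial peroxiredoxin, rose (0.56). For the 5 aryl-alcohol dehydrogenases, 3 rose and 0 fell (4 and 0 adjusted over the list alone): median log2 change 0.34, adjusted p = 0.000296, and adjusted p = 0.234 with an estimated correlation. AAD6 rose at least 3.03-fold over controls at the level of the deleted loci, and AAD4, on a probe set shared with similar sequences, rose by 0.90. The other probe set of AAD4, dimmer and left out of the tests of genes, rose by 0.349.

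Lists of nitrogen, sulfur, zinc and phosphate, and vitamin genes shifted up at 200 mg/L at the preset correlation, though most members of the nitrogen, sulfur and vitamin lists did not pass and 4 zinc and phosphate genes fell. Of 30 genes of nitrogen catabolite repression and amino acid transport, 13 rose and 1 fell (14 and 1 adjusted over the list alone): median log2 change 0.27, adjusted p = 0.000147, and adjusted p = 0.234 with an estimated correlation. The ammonium permease MEP2 (1.11), DAL3 of allantoin use (0.98) and the GABA transaminase UGA1 (0.58) rose, and CAR2 of arginine use fell (-0.77). In sulfur amino acid metabolism, 11 rose and 3 fell (12 and 3 adjusted over the list alone) of 36 genes: median log2 change 0.085, adjusted p = 0.00502, and adjusted p = 0.234 with an estimated correlation. MET28 (at least 2.76-fold) and MET2 (at least 1.5-fold), both over controls below 228.8, STR3 (1.15) and the methionine permease MUP3 (0.71) rose. For zinc and phosphate starvation, 10 rose and 4 fell (12 and 4 adjusted over the list alone) of 21: median log2 change 0.22, adjusted p = 0.00381, and adjusted p = 0.234 with an estimated correlation. PHO5 (1.49), PHO89 (1.25) and PHO11 (1.13) rose and the zinc transporter ZRT1 fell (-0.44). In vitamin B1 and B6 metabolism, 6 rose and 1 fell (8 and 1 adjusted over the list alone) of 17: median log2 change 0.15, adjusted p = 0.00502, and adjusted p = 0.133 with an estimated correlation. SNO1 rose (0.56).

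Lists of carbon metabolism, sterol and wall genes shifted up at 200 mg/L at the preset correlation. Of 30 genes of the tricarboxylic acid and glyoxylate cycles, 12 rose and 1 fell (16 and 3 adjusted over the list alone): median log2 change 0.14, adjusted p = 0.0103, and adjusted p = 0.297 with an estimated correlation. The citrate synthases CIT3 (at least 1.18-fold, over controls below 228.8) and CIT1 (0.44), PCK1 (0.65) and PYC1 (0.65), both at the branch to glucose synthesis, rose. Of 20 glycolysis genes, 5 rose and 0 fell (5 and 0 adjusted over the list alone): median log2 change 0.055, adjusted p = 0.00101, and adjusted p = 0.234 with an estimated correlation. TDH1 (0.48) and GLK1 (0.44) rose. In ergosterol synthesis, 7 rose and 0 fell (7 and 0 adjusted over the list alone) of 28: median log2 change 0.054, adjusted p = 0.0216, and adjusted p = 0.234 with an estimated correlation, and ERG3 rose by 0.45. In cell wall integrity, 13 rose and 2 fell (13 and 2 adjusted over the list alone) of 38: median log2 change 0.075, adjusted p = 0.0216, and adjusted p = 0.234 with an estimated correlation. The protease YPS3 (0.51) and the glucan synthase GSC2 (0.40) rose and CWP1 fell. Without IC20 control array 2 and 200 mg/L array 1 together, an alternative chosen after seeing the data, the ergosterol list had adjusted p = 0.0531 and the cell wall list adjusted p = 0.0504.

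Vacuolar and stationary phase genes also shifted up at 200 mg/L. Of 25 genes of autophagy and vacuolar proteases, 7 rose and 3 fell (10 and 3 adjusted over the list alone): median log2 change 0.080, adjusted p = 0.0456, and adjusted p = 0.448 with an estimated correlation. The vacuolar mannosidase AMS1 rose (0.78). The autophagy call was lost without IC20 control array 1 (adjusted p = 0.0645), IC20 control array 2 (adjusted p = 0.110), 200 mg/L array 1 (adjusted p = 0.135) and 200 mg/L array 2 (adjusted p = 0.0976), and with quantile normalization (adjusted p = 0.0882). It was also lost with the replicate number as a block (adjusted p = 0.0503), though the numbers do not pair the arrays. Of 23 stationary phase genes, 5 rose and 0 fell (5 and 0 adjusted over the list alone): median log2 change 0.042, adjusted p = 0.0391, and adjusted p = 0.504 with an estimated correlation. RTS3 (1.40) and the membrane stress protein HSP12 (0.69) rose. The stationary phase call was lost without IC20 control array 1 (adjusted p = 0.0700), 200 mg/L array 1 (adjusted p = 0.142) and 200 mg/L array 2 (adjusted p = 0.112). The replicate block ended the stationary phase call as well (adjusted p = 0.0527). Without IC20 control array 2 and 200 mg/L array 1 together the autophagy list had adjusted p = 0.228 and the stationary phase list adjusted p = 0.0827.

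Lists of ribosome, polymerase, chaperone and proteasome genes shifted down at 200 mg/L at the preset correlation. Log2 changes at this dose went with coding length (Spearman's rho = 0.17 across genes, against 0.053 at 110 mg/L). Of 128 cytosolic ribosomal protein genes, most of them short, 0 rose and 2 fell (0 and 0 adjusted over the list alone): median log2 change -0.061, adjusted p = 1.79e-06, and adjusted p = 0.468 with an estimated correlation. With the length trend removed, chosen after seeing the data, the list had adjusted p = 0.000589. In ribosome biogenesis, 1 rose and 12 fell (1 and 12 adjusted over the list alone) of 77: median log2 change -0.10, adjusted p = 5.31e-06, and adjusted p = 0.467 with an estimated correlation. The RNA helicases DBP8 (-0.35) and DBP2 (-0.29) fell. Of 31 heat shock and chaperone genes, 3 rose and 8 fell (4 and 14 adjusted over the list alone): median log2 change -0.12, adjusted p = 0.0273, and adjusted p = 0.273 with an estimated correlation. HSP31, a glyoxalase of the chaperone list, rose (0.52). Of 27 genes of RNA polymerases I and III, 0 rose and 3 fell (0 and 2 adjusted over the list alone): median log2 change -0.10, adjusted p = 0.0216, and adjusted p = 0.448 with an estimated correlation. Leaving out IC20 control array 1 (adjusted p = 0.0605) and IC20 control array 2 (adjusted p = 0.107) ended the call each time, as did leaving out IC20 control array 2 and 200 mg/L array 1 together (adjusted p = 0.0765). Proteasome genes shifted down, with 0 rose and 4 fell (0 and 0 adjusted over the list alone) of 35: median log2 change -0.064, adjusted p = 0.0213, and adjusted p = 0.234 with an estimated correlation. This call ended without IC20 control array 2 (adjusted p = 0.0685) and without both arrays together (adjusted p = 0.0586).

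In all, 971 genes passed at 200 mg/L by limma with Benjamini-Hochberg adjusted p under 0.05: 546 rose (56.2%) and 425 fell, 46 and 7 of them by at least 2-fold. The split was 462 higher and 547 lower (45.8% higher) after median centring. Fitted on only the 6 arrays of its experiment, 444 genes passed, and 39 of 145 named genes lost their call. At 110 mg/L such a fit gave 314 genes, more than with all arrays. The median SD of a gene was larger in the IC20 experiment (0.0823 and 0.0947) than in the LOEC experiment (0.0559 and 0.0566). The main fit shares its estimate of the spread over both. Its SE and adjusted p thus tend to be too small at 200 mg/L and too large at 110 mg/L. The smaller fits have fewer degrees of freedom at both doses, which alone would not raise the count at 110 mg/L. The counts at the doses thus do not measure the effect of dose alone.

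**Figure D2:**
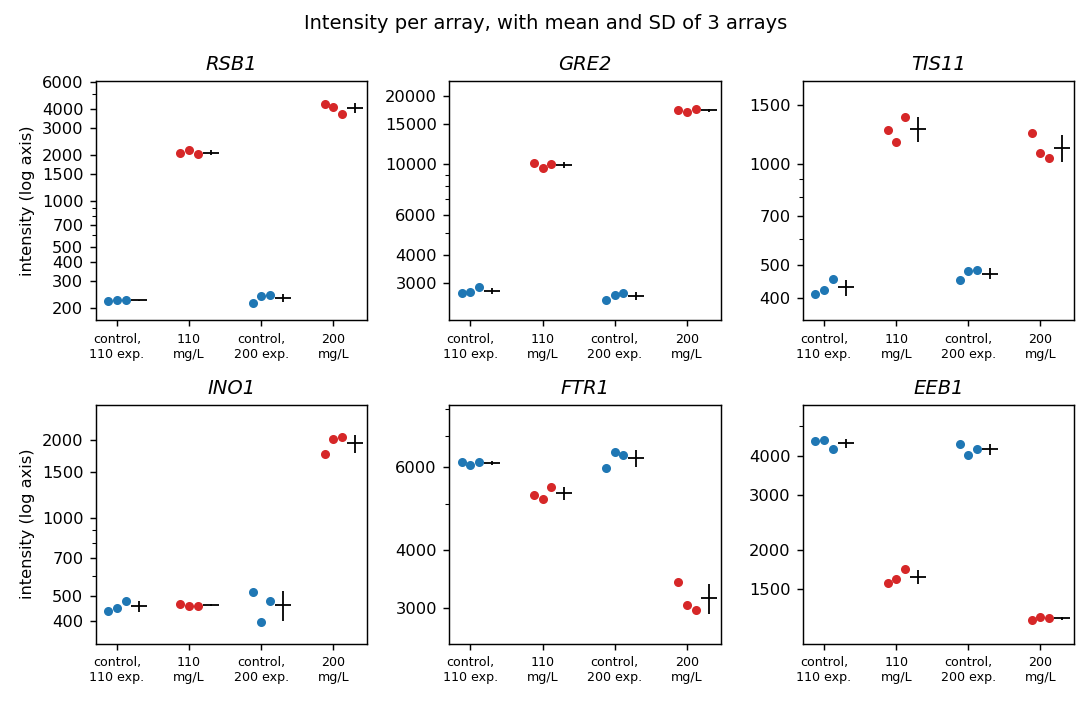
Intensity on each of the 12 arrays (log axis) for 6 genes, with controls in blue, treated arrays in red, and the mean with its SD over 3 arrays as a black cross. RSB1 and GRE2 rose at both doses, INO1 was level with its controls at 110 mg/L (462 against 456) and reached 1943 at 200 mg/L, and FTR1 was down to 3146 at 200 mg/L.

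The responses at both doses were next set side by side. RSB1, GRE2, YGP1, CIS1, ICT1 and YOR1 rose and EEB1, CWP1, WSC4 and PDR12 fell at both doses. Of the 166 genes higher at 110 mg/L, 153 were also higher at 200 mg/L, and of the 66 lower genes 57 were lower again. Independent calls would give 16.6 and 5.1. The calls share each gene's estimate of the spread and are not independent, so these numbers are not a chance level. In the genes called the same way at both doses, the change at 200 mg/L was 1.36 times (higher) and 1.32 times (lower) the change at 110 mg/L in the median. OPI3, a methyltransferase of phosphatidylcholine synthesis, was called in opposite directions, with -0.14 at 110 mg/L and 0.21 at 200 mg/L. Its call at 110 mg/L was lost without any 1 of the 6 arrays of that experiment, at adjusted p from 0.0907 to 0.168. Across the 5449 genes the log2 changes correlated at Pearson's r = 0.646 and Spearman's rho = 0.537, where genes are not independent replicates. Some lists that shifted at 110 mg/L did not pass camera at 200 mg/L. They were the G1 and S phases (median log2 change 0.012, adjusted p = 0.939) and the later phases (-0.017, 0.418). Gcn4 genes (0.069, 0.0715), peroxisome and beta-oxidation (-0.067, 0.333) and phospholipid synthesis (-0.054, 0.588) did not pass either.

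**Figure D3:**
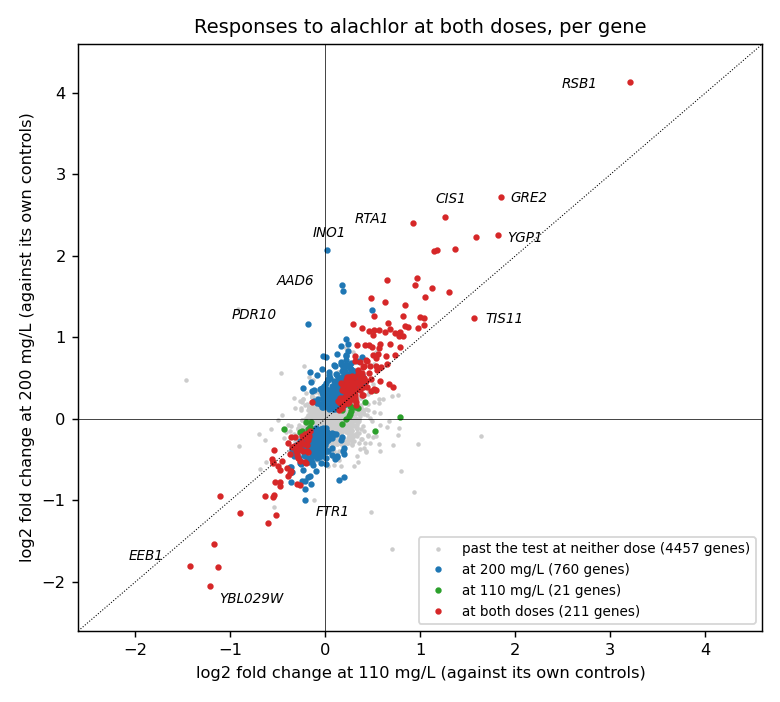
Log2 fold change of each of 5449 genes at 110 mg/L (x axis) and at 200 mg/L (y axis), each against its own controls, coloured by the doses at which the gene passed at adjusted p under 0.05. The dotted line marks equal change. Of these genes, 211 passed at both doses, 760 at 200 mg/L and 21 at 110 mg/L, and most genes past the test at both doses lie beyond the line at 200 mg/L.

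The difference between the responses was tested directly, each response being taken against its own controls. By fitted value INO1 differed the most, with a log2 change of 0.018 at 110 mg/L and 2.07 at 200 mg/L (difference 2.06, SE 0.13, adjusted p = 9.89e-06). The rises of RTA1 (difference 1.49), CIS1 (1.22), RSB1 (0.92), GRE2 (0.88) and YOR1 (0.72) were larger at 200 mg/L. The controls of RTA1 and AAD6 read below 228.8 or near it, those of RSB1 near it, and FRE4 at 200 mg/L below it, so the size of their differences is not exact. PDR10 (1.34), AAD6 (1.47), the uncharacterized YLL056C (1.39), AAD4 (0.73), MEP2 (0.73) and the mitochondrial carnitine carrier CRC1 (0.87) also had higher responses at 200 mg/L. The value of AAD4 rests on the brighter of its 2 probe sets, and the other rose less at 200 mg/L (0.349). FTR1 (-0.78, adjusted p = 0.000402) and FRE4 (-0.67, adjusted p = 0.00115) had lower ones: FRE4 rose at 110 mg/L and had a log2 change of -0.15 at 200 mg/L.

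By list, the Pdr1 and Pdr3 targets differed the most, with 9 genes higher and 0 lower at 200 mg/L (13 and 0 adjusted over the list alone): median difference 0.53, adjusted p = 8.42e-26, and adjusted p = 0.00107 with an estimated correlation, which kept the call. Nitrogen genes (median difference 0.17, adjusted p = 2.17e-06, and adjusted p = 0.262 with an estimated correlation) and aryl-alcohol dehydrogenases (0.16, adjusted p = 3.28e-05, and adjusted p = 0.257 with an estimated correlation) had higher responses at 200 mg/L. Genes of the G1 and S phases had lower ones (-0.13, adjusted p = 4.47e-05, and adjusted p = 0.114 with an estimated correlation), as did ribosomal proteins (-0.062, adjusted p = 4.29e-09, and adjusted p = 0.477 with an estimated correlation). The G1 and S phase list did not itself fall at 200 mg/L, with a median log2 change of 0.012 there. In all, 68 genes passed by limma, 54 with a higher and 14 with a lower response at 200 mg/L. With array weights, whose estimation stopped before convergence, 393 passed, 190 higher and 203 lower, so that the balance of directions was not kept. Dose and experiment cannot be told apart in this comparison. The count was 45 and 42 without LOEC control arrays 1 and 2, 39 and 41 without 110 mg/L arrays 1 and 3, 39 without IC20 control array 1, and 43 without 200 mg/L array 2.

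The controls of the experiments were compared to see how far the experiments differ without herbicide. YBL100W-A, a gene of the Ty retrotransposon family named here after its values were seen, was 16.0-fold higher in the IC20 controls, at 5546 ± 1520 against 338 ± 43.5 (SD, n = 3; log2 difference 4.0, SE 0.27, adjusted p = 3.99e-05). Of the genes described above, AAD6 was higher in the IC20 controls (adjusted p = 0.0266), with both means below 228.8, whereas INO1 (0.014) and RSB1 (0.047) did not pass. In all, 43 genes passed by limma, 32 higher and 11 lower in the IC20 controls, 5 of the higher ones by at least 2-fold. Array weights gave 579, 357 higher and 222 lower, and without the 20% dimmest probe sets 20 passed. The count was 22, 5 and 10 without LOEC control arrays 1, 2 and 3, and 12, 17 and 5 without IC20 control arrays 1, 2 and 3.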

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

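Of the tests below, those on the cause of the INO1 difference, the structure of the regroupings and the 2 arrays left out together were chosen after the result was seen. The response to alachlor differed between the doses for 68 genes by the limma test of the difference itself, and of the genes named by rule 31 had a higher and 6 a lower response at 200 mg/L.

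INO1 had the largest fitted difference, 2.06 (adjusted p = 9.89e-06), with no change past the test at 110 mg/L and a rise by 2.07 at 200 mg/L in 3 of 3 arrays. A difference between the controls of the experiments is argued against, since these differed by 0.014. The difference was at least 2.06 after quantile normalization and median centring, and 2.05 after the length trend was removed. Array scaling and the length trend are thus too small to make it up. For a single gene this could hardly have come out otherwise, since the array medians already lay within 1561.3 to 1613. These settings therefore lend no support to a response to the dose. That INO1 responds to the dose stays a hypothesis. Dose and experiment are confounded in the difference, and no other test here separates them.

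Of drug resistance and export genes, the following had higher responses at 200 mg/L, by log2 differences: RTA1 (1.49), PDR10 (1.34), CIS1 (1.22), RSB1 (0.92), GRE2 (0.88), YOR1 (0.72), ICT1 (0.65), TPO4 (0.57) and FLR1 (0.51). So had genes of compound handling, AAD6 (1.47), AAD4 (0.73), GTT2 (0.51), ECM4 (0.48) and BDH2 (0.92), of nitrogen and sulfur supply, DAL3 (0.76), MEP2 (0.73), UGA1 (0.38) and MET28 (0.70), and of carbon use and mitochondria, MPC3 (0.90), CRC1 (0.87), CIT3 (0.60) and PYC1 (0.55). The other higher responses were those of YLL056C (1.39), DIT1 (0.62), HSP12 (0.53), HMX1 (0.52), GSC2 (0.41), OPI3 (0.36), MGT1 (0.32) and URA2 (0.27). Lower responses at 200 mg/L were those of EEB1 (-0.38), PHO3 (-0.67), FRE4 (-0.67), FTR1 (-0.78), YBL029W (-0.84) and GAT2 (-0.90). FLR1 and GAT2, a transcription factor of the GATA family, passed narrowly (adjusted p = 0.04999 for both). RSB1, RTA1, AAD6, MET28, CIT3, DIT1, YBL029W and FRE4 read below or near 228.8, the highest reading of LEU2, URA3 and MET17, in some of the groups compared, so the size of their differences is not exact. Of the 37 genes, 14 lost their call when some single array was left out: DIT1, ECM4, EEB1, FLR1, GAT2, GSC2, GTT2, HMX1, HSP12, ICT1, MGT1, TPO4, UGA1 and URA2.

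By list, the median difference was 0.53 for Pdr1 and Pdr3 targets, 0.17 for nitrogen genes, 0.16 for aryl-alcohol dehydrogenases, 0.089 for drug antiporters, 0.076 for glutathione genes, 0.068 for autophagy and vacuolar proteases, 0.055 for the tricarboxylic acid and glyoxylate cycles, 0.056 for stationary phase genes, 0.036 for ergosterol synthesis and 0.035 for oxidative stress genes under Yap1. It was -0.091 for the iron regulon, -0.13 for the G1 and S phases and -0.062 for ribosomal proteins. These 13 lists passed with the preset correlation, and of them the Pdr1 and Pdr3 targets passed with an estimated correlation (adjusted p = 0.00107). Of these calls, 7 were lost when some single array was left out, in fits that also have fewer arrays. The antiporter list lost its call without IC20 control array 2 (adjusted p = 0.0629). The Yap1 list lost its call without IC20 control array 1 (adjusted p = 0.0742) and 200 mg/L array 1 (adjusted p = 0.147). The ergosterol list lost its call without LOEC control array 1 (adjusted p = 0.0760), 110 mg/L array 2 (adjusted p = 0.0736), IC20 control array 2 (adjusted p = 0.0629) and 200 mg/L array 1 (adjusted p = 0.120). The tricarboxylic acid list lost its call without LOEC control array 3 (adjusted p = 0.0812), 110 mg/L array 2 (adjusted p = 0.0607), IC20 control array 1 (adjusted p = 0.0865) and 200 mg/L array 1 (adjusted p = 0.129). The iron list lost its call without 200 mg/L array 1 (adjusted p = 0.0581). The autophagy list lost its call without LOEC control array 3 (adjusted p = 0.0812), IC20 control array 2 (adjusted p = 0.0894), 200 mg/L array 1 (adjusted p = 0.120) and 200 mg/L array 2 (adjusted p = 0.0703). The stationary phase list lost its call without LOEC control array 3 (adjusted p = 0.191), IC20 control array 1 (adjusted p = 0.0736), 200 mg/L array 1 (adjusted p = 0.242) and 200 mg/L array 2 (adjusted p = 0.0703). Without IC20 control array 2 and 200 mg/L array 1 together, the calls of the Yap1 (adjusted p = 0.119), ergosterol (0.124), tricarboxylic acid (0.119), autophagy (0.217) and stationary phase lists (0.133) were lost.

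Among 100 regroupings of the experiment labels, 10 gave at least the 68 genes of the real grouping, itself included, the highest of the others 1080. Regroupings that call many times the real number point to a structure of the samples. All 10 kept the treated arrays of each dose together, so they still hold the difference between the doses. The real grouping holds that difference too, so it alone cannot account for the higher counts. The others among the 10 exchange the controls, so a difference between the experiments is no longer cancelled by own controls. The highest count among regroupings that did not keep the treated arrays together was 1. For the 13 lists, 4 of 100 regroupings gave as many, the real one included, with 18 as the highest of the others. Of these 4, 1 mixed the treated arrays of the doses and called 0 genes, yet shifted 13 lists, as many as the real grouping. Regroupings that keep them together are not free of the dose, so whether chance can be excluded is left open for both counts.

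Of the 218 probe sets tied to no gene, 8 were higher and 3 lower at 110 mg/L and 28 higher and 17 lower at 200 mg/L. Probe set 1776865_at went from 145 ± 6.87 to 7945 ± 466 (SD, n = 3) at 200 mg/L, a fitted log2 change of 5.77. Its controls read below 228.8, so that value is not exact, and the rise is bounded as at least 34.7-fold. At 110 mg/L it rose at least 2.00-fold. Probe set 1774184_at rose by 2.02 at 200 mg/L, and 1777669_at had the largest fall, -0.95. What these probe sets measure is not given in the sources used here.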

How the results depend on the processing

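The tests chosen after the result was seen are those with the length trend removed, those without IC20 control array 2 and 200 mg/L array 1, the count of arrays that correlate best with their own number, and the count of calls as dim as the deleted loci. No named gene or list past the test turned its direction under the alternatives in which it was fitted. Lists were not tested with array weights, the intensity trend, only the arrays of an experiment or all probe sets. Nor were they tested without the 20% dimmest probe sets or at the stricter thresholds. Without those probe sets, 53 of 68 named genes kept a value at 110 mg/L and 110 of 145 at 200 mg/L. For the difference, 25 of 37 did. Of the named genes past the test, 19 of 68 at 110 mg/L, 30 of 145 at 200 mg/L and 14 of 37 for the difference lost their call when some single array was left out, as did 3 of 16, 4 of 21 and 7 of 13 lists. With each array left out in turn the counts ran from 113 to 184 genes at 110 mg/L, 713 to 973 at 200 mg/L, 39 to 68 for the difference and 5 to 22 for the controls, and the lists from 14 to 20, 18 to 23 and 7 to 16. Fewer arrays were fitted. Pearson's r between the responses ran from 0.576 to 0.691.

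Stricter thresholds call fewer genes by construction: adjusted p under 0.01 left 108, 481, 32 and 7 genes, in the order above, and a change of at least 2-fold 19, 53, 8 and 5. With only the 6 arrays of the experiment, 314 genes passed at 110 mg/L, more than with all arrays, and 444 at 200 mg/L, fewer. With the replicate number as a block, 97, 519 and 21 genes passed at 110 mg/L, at 200 mg/L and for the difference. The numbers do not pair the arrays, since 1 of 12 arrays correlated best with its own number and the correlations of equal numbers ran from -0.615 to 0.144. Array weights gave 2132, 1182, 393 and 579 genes and r = 0.574. The weights were 7.24 on LOEC control array 2 and 6.17 on 110 mg/L array 1 against 0.284 to 2.14 on the others, the estimation stopped before convergence, and the cause was not tested. Without the 20% dimmest probe sets, 20 genes differed between the controls and r was 0.791, and with log2 of the value plus 16 r was 0.714, both of which leave out or damp dim probe sets. With an estimated correlation 4, 1 and 1 lists passed. The length trend removed gave 322, 1184, 88 and 57 genes, and leaving out both arrays 765 at 200 mg/L and 52 for the difference. No other alternative moved a count by more than 1.5 times.

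Signal over background limits dim genes: probe sets of LEU2, URA3 and MET17, deleted in the strain, read up to 228.8, each probe set with a level of its own. HIS3, the remaining locus of that list, read 6721 to 9552 and was not used for this level. Of the calls, 16 at 110 mg/L and 90 at 200 mg/L had a mean below 228.8 in at least 1 of the groups compared, and 10 and 64 in both. RSB1 at 110 mg/L is among the former, and the fitted size of such changes, or of a difference built on them, is not exact.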

Other observations

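The tests on the Ty probe set, the test for a wrong label of IC20 control array 2, the settings with the length trend removed, and the look at COR1 and at genes that separate the experiments were chosen after the result was seen. Some gene groups did not shift as lists at either dose while single members changed. Of 38 genes of fatty acid and sphingolipid synthesis, 4 rose and 0 fell at 110 mg/L and 10 and 4 at 200 mg/L (6 and 1, and 10 and 5, adjusted over the list alone; median log2 change 0.016 and 0.016, adjusted p = 0.106 and 0.110). Besides RSB1, the ceramide synthase subunit LAC1 (0.30 and 0.38) and the sphingoid base hydroxylase SUR2 (0.33 and 0.44) rose at both doses. Of 40 general stress genes under Msn2 and Msn4, 3 rose and 2 fell at 110 mg/L and 10 and 5 at 200 mg/L (4 and 3, and 12 and 5, adjusted over the list alone; median log2 change 0.073 and 0.063, adjusted p = 0.0919 and 0.114). YGP1 and YRO2 (0.77 and 1.01) rose at both doses. In 17 hexose transporter genes, 0 rose and 2 fell at 110 mg/L and 2 and 3 at 200 mg/L (1 and 3, and 3 and 5, adjusted over the list alone; median log2 change 0.10 and -0.15, adjusted p = 0.900 and 0.288), and at 110 mg/L the test pointed down while the median was positive. HXT2 fell at both doses (-0.48 and -0.78). For oxidative phosphorylation, 0 rose and 1 fell at 110 mg/L and 2 and 4 at 200 mg/L (0 and 1, and 2 and 4, adjusted over the list alone; median log2 change 0 and -0.010, adjusted p = 0.298 and 0.588) of 36 genes, and COX5B, the cytochrome oxidase subunit of low oxygen, fell (-0.35 and -0.35). In purine and pyrimidine synthesis, 1 rose and 0 fell at 110 mg/L and 5 and 1 at 200 mg/L (2 and 0, and 6 and 1, adjusted over the list alone; median log2 change 0.037 and 0.027, adjusted p = 0.0919 and 0.344) of 26. URA10 rose at 200 mg/L (0.44).

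Genes of DNA repair, protein folding in the secretory pathway, chromatin and cell type did not shift as lists. Of 26 DNA damage genes, 1 rose and 0 fell at 110 mg/L and 3 and 1 at 200 mg/L (1 and 0, and 3 and 1, adjusted over the list alone; median log2 change 0.020 and 0.032, adjusted p = 0.634 and 0.418), where at 110 mg/L the mean, -0.001, and the test differ in sign from the median. RAD16 of excision repair fell at 200 mg/L (-0.43) and MGT1, a DNA methyltransferase repair enzyme, rose (0.25). In the unfolded protein response, 0 rose and 0 fell at 110 mg/L and 1 and 1 at 200 mg/L (0 and 0, and 1 and 1, adjusted over the list alone; median log2 change -0.014 and -0.035, adjusted p = 0.366 and 0.604) of 25, with a mean of 0.009 at 110 mg/L. For 9 histone genes, 0 rose and 0 fell at 110 mg/L and 0 and 0 at 200 mg/L (0 and 0, and 0 and 0, adjusted over the list alone; median log2 change 0.023 and -0.005, adjusted p = 0.992 and 0.609), with 1 and 0 under an unadjusted p of 0.05 in limma. At 110 mg/L the test pointed down while the median was positive. Of 8 a-cell genes, 0 rose and 0 fell at 110 mg/L and 0 and 0 at 200 mg/L (0 and 0, and 0 and 0, adjusted over the list alone; median log2 change -0.014 and 0.047, adjusted p = 0.992 and 0.418), with 1 and 2 under an unadjusted p of 0.05 in limma, and a mean of 0.019 at 110 mg/L. The pheromone gene MFA1 read 16260 ± 243 in the IC20 controls and 17400 ± 795 at 200 mg/L (SD, n = 3). Of 4 alpha-cell genes, 0 rose and 0 fell at 110 mg/L and 2 and 0 at 200 mg/L (2 and 0, and 2 and 0, adjusted over the list alone; median log2 change 0.24 and 0.23, adjusted p = 0.106 and 0.0883). MF(ALPHA)1 read 28.4 ± 2.83 and 31.3 ± 6.74 in the same groups, and STE3 passed at 200 mg/L, at 115 ± 8.06 and 190 ± 11.4, within the readings of deleted loci. SAG1, the other gene that rose, read far above them, at 1200.5 to 1429.8 in the IC20 controls and 1462.5 to 1830.8 at 200 mg/L. In the pheromone response, 2 rose and 1 fell at 110 mg/L and 4 and 2 at 200 mg/L (4 and 2, and 4 and 3, adjusted over the list alone; median log2 change -0.071 and -0.069, adjusted p = 0.274 and 0.591) of 20. AGA1, an anchor of agglutinin, fell at 110 mg/L (-0.36). In sporulation and meiosis, 1 rose and 0 fell at 110 mg/L and 5 and 2 at 200 mg/L (1 and 0, and 5 and 2, adjusted over the list alone; median log2 change 0.058 and 0.043, adjusted p = 0.234 and 0.591) of 32. DIT1, of the spore wall, passed at both doses, and at 200 mg/L rose at least 1.13-fold over controls at the level of the deleted loci.

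Of the loci changed in BY4741, 0 rose and 0 fell at 110 mg/L and 1 and 0 at 200 mg/L (0 and 0, and 1 and 0, adjusted over the list alone; median log2 change 0.20 and -0.14, adjusted p = 0.205 and 0.955). LEU2, URA3 and MET17 read at means of 186.2, 26.1 and 133.9 over the 12 arrays. BY4741 carries a deletion at HIS3 as well, yet its probe set read far above these, and whether that probe set lies outside the deleted part or the strain differs from its label is not given in the sources used here. It read 7325 ± 534 in the IC20 controls and 8816 ± 802 at 200 mg/L (SD, n = 3), a log2 change of 0.27 (adjusted p = 0.0251) that was lost without IC20 control array 1 (adjusted p = 0.0865), 200 mg/L array 1 (0.0689) or 200 mg/L array 2 (0.0717). COR1, a subunit of the respiratory chain named after its values were seen, read 19959 in IC20 control array 3 and 2184 to 2660 in the other 11 arrays.

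YBL100W-A, a Ty retrotransposon gene read by a probe set shared between similar sequences, was higher in every IC20 array than in every LOEC array, the lowest of the former being 9.01 times the highest of the latter. The controls differed by 3.96 after quantile normalization and by 3.98 with the length trend removed. Array scaling and the length trend are thus too small to make up the difference. For a single gene this could hardly have come out otherwise, since the array medians already lay within 1561.3 to 1613. Other causes are not narrowed down by it. A difference between the cultures, strain stocks or array handling of the experiments cannot be told apart here, since each experiment is 1 unit of the design. No biological explanation was tested, since the design gives none. YBL005W-A (lowest over highest 1.98) and YAR010C (1.74), also Ty genes, and WHI3 (1.47) and YBL112C (1.5), all picked after their values were seen, were separated the same way. So were ECM2 and BSC5, with no ratio given since the readings it would compare lie below 228.8 on both sides.

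IC20 control array 2 and 200 mg/L array 1 deviated together from their group means, with r = 0.648 across genes, which are not independent. Shared deviation was not confined to this pair. IC20 control array 1 had r = 0.45 with 200 mg/L array 3 and -0.615 with array 1, and IC20 control array 2 had -0.481 with array 3. The remaining pairs of a control and a treated array in this experiment lay between -0.196 and 0.194. A trend with coding length as the whole cause is argued against, since r was 0.568 with it removed, and normalization is argued against, since r was 0.664 after quantile normalization. A treated array labelled as that control is argued against, since the Pdr1 and Pdr3 targets in it lay at a median of -0.087 (-0.393 to 0.081) from the other IC20 controls. In Spearman's rho with coding length, IC20 control array 2 (-0.464) and 200 mg/L array 1 (-0.488) had the same sign. So had IC20 control array 1 (0.396) and 200 mg/L array 3 (0.57), while the pairs at -0.615 and -0.481 had opposite signs. Pairs with 200 mg/L array 2 (rho = -0.155) did not follow these signs. What the pair shares beyond a length trend stays open, and no label used here gives a day or batch.

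For 110 mg/L, 200 mg/L and the controls, each with 10 splits of 6 arrays, the splits are too few for a share under 0.05. At 110 mg/L 232 genes passed in the real split and at most 0 in another, at 200 mg/L 971 and 59, and for the controls 43 and 0, so that 1 split of 10, the real one, gave as many in each. Every other split mixes the groups compared, which moves their difference into the spread within groups. Low counts there are thus partly built in and are not a null count. The split with 59 genes put IC20 control array 2 with 200 mg/L arrays 1 and 2, and so kept together the pair that deviated together. By list, 16 passed at 110 mg/L against at most 11 in another split, and 21 at 200 mg/L against 17, again in 1 split of 10.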
